A study of Mus musculus with 48 samples.

How the data were processed

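Gene expression was measured by bulk RNA-seq in 48 mouse libraries, 16 from sorted prostate cells in 4 groups and 32 from the CaP2 and CaP8 cell lines in 10 groups. Samples were grouped by their labels, by cell type and castration for the prostate and by line and treatment for the cells. RNA was isolated with a Qiagen column kit, and 1 µg went into each library, prepared with a Vazyme kit, per the labels' protocols. Reads were trimmed with Trim Galore 0.6.7 and cutadapt 3.4, aligned with STAR 2.7.4a to the mouse genome build GRCm39 and handled with SAMtools 1.7, per the submitters' processing notes. The deposited values are counts, made with featureCounts 2.0.1 from paired reads over the exons of a GENCODE annotation, with no strand setting, per the file headers. Cell line libraries were counted by gene name and prostate libraries by Ensembl gene ID, per the file headers. Where several gene IDs share a name, the cell line counts hold their sum. Each library has its own file, and a joined table per experiment repeated the same counts in all 32 cell line and all 16 prostate columns.

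No row lacked a gene name or ID, so all counts entered the library totals. Because the counting ignored strand, reads from a gene and an overlapping antisense gene cannot be told apart, and members of near-identical families such as the Sprr2, Saa and MHC genes and the mitochondrial genes with nuclear copies are less certain than single-copy genes. The 18S gene Rn18s-rs5 held the largest share of the counts in every library. Total counts ran from 13222627 to 24107973 in the prostate and from 15477236 to 27610603 in the cell lines, and mitochondrial genes took 1.83% to 7.01% and 1.51% to 4.68%. At these depths the spread between libraries limits precision. The common biological coefficient of variation was 0.343 in the prostate, 0.139 in CaP2, 0.118 in CaP8 and 0.129 over both lines.

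Differential expression was computed from the deposited counts in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr, robust dispersion and robust quasi-likelihood fit, F test) and Benjamini-Hochberg adjustment, with calls at an adjusted p under 0.05. A group-means model without covariates was fitted to the 16 prostate libraries (17128 genes tested), the CaP2 libraries (13374), the CaP8 libraries (13628) and, for differences between lines, all 32 cell line libraries (14457). Comparisons were castrated against control in each sorted cell type, the difference of these changes, epithelium against fibroblasts, each treatment against vehicle, SB431542 with TGFβ against TGFβ, the interaction of both ligands, and the differences between lines. FGF9 with TGFβ against FGF9 was added after the file headers showed a pair of sequencing folders. CPM values use TMM-scaled library sizes, and log2 fold changes are those of the edgeR fit.

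The text uses 35 gene lists of 738 members (674 different genes, 671 of them named in the files), of which 621 genes were measured in the prostate, 405 in CaP2 and 412 in CaP8. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Genes were named by a fixed rule: for castration and for TGFβ and FGF9 against vehicle, the 8 largest rises and the 8 largest falls among called genes with a mean of at least 5 CPM and no overlap between the groups. For other comparisons the rule took 4 per direction. It also took up to 2 members per direction of each list described, and a fixed set of design and control genes such as Pten, Ar, Tgfb1 and Dusp6. Overlaps between lines were compared with a one-sided Fisher's exact test.

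The alternatives were DESeq2 1.42.0, RLE size factors, no expression filter, only the groups compared in the fit, the replicate number as a block, the joined tables, each run of library numbers alone, contaminant lists taken out, a 1.5-fold minimum for overlaps, and leaving out each library in turn. Alternatives added after the data were seen were the sequencing folder as a term, which the file headers give for the cell lines, and the removal of genes over 4-fold higher in epithelium than in fibroblasts. Outlying libraries were looked for with Dixon's Q in groups of 4 and 5 libraries, and other splits of the samples were refitted, at most 100 per comparison.

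The fits were tested on simulated data in which 200 genes were changed by 1.5-fold, 2-fold or 4-fold. For castration in epithelium, 4.48%, 20% and 62.5% of the changed genes were recovered at these sizes, in fibroblasts 7.46%, 23.9% and 68.8%, and for the difference of both 0%, 9.23% and 46.0%. For TGFβ against vehicle the shares were 38.8%, 67.2% and 93.9% in CaP2 and 52.2%, 70.1% and 86.4% in CaP8, and for FGF9 against vehicle 53.0%, 72.7% and 87.9% in CaP2 and 59.7%, 70.1% and 90.9% in CaP8. For the interaction they were 28.4%, 50% and 78.8% in CaP2 and 29.9%, 58.2% and 78.8% in CaP8. For the line difference of the FGF9 response they were 34.8%, 56.7% and 72.7%, and of the TGFβ response 17.9%, 59.7% and 77.3%. Unchanged genes made up 2.78% to 9.68% of the calls, no recovered gene had the wrong sign, and camera called the changed set and 0 of 20 unchanged sets in each comparison. The simulated genes were drawn independently, so these sets do not test camera on lists whose members are correlated. The simulations held no effects of sequencing folder or library run, so the recovered and false shares may not hold where such effects exist. Figures were drawn with matplotlib 3.10.9.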

Results

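RNA-seq counts of 48 mouse libraries were deposited, from 2 kinds of material. The first is prostate tissue of mice in which a probasin-driven Cre removes Pten in prostate epithelium, a model of prostate cancer. Epithelial cells and fibroblasts were sorted by flow cytometry from control mice (n = 3 libraries per cell type) and mice castrated at week 10 (n = 5 per cell type), which made 16 libraries. The second is CaP2 and CaP8, a pair of Pten-null mouse prostate epithelial lines, with 32 libraries. The labels call the lines epithelial, but in vehicle cells Krt8 averaged 2.20 CPM in CaP2 and 6.0 in CaP8 beside 4194 and 1150 CPM of the collagen gene Col1a1, and the CaP2 libraries together held 3 counts of Epcam and 0 of Krt5, the CaP8 libraries 33 and 7. Each line was given vehicle (n = 4), or 1 of 4 treatments (n = 3 each): TGFβ for 1 h, FGF9 for 0.5 h, both ligands, or the TGFβ receptor kinase inhibitor SB431542 for 2 h with TGFβ. The total count per library ran from 13222627 to 24107973 (median 16419032.5) in the prostate and from 15477236 to 27610603 (median 19388097.5) in the cell lines. The 18S ribosomal RNA gene Rn18s-rs5 took 2.88% to 19.3% of the counts of a prostate library and 9.22% to 15.9% of those of a cell line library. P-values here measure the spread between libraries only, since the labels do not say whether replicates came from separate animals, pools or cultures.

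Pten, the gene deleted in this model (ENSMUSG00000013663.8, GRCm39 chromosome 19, 32734897 to 32803560), was counted in every group. It stood at 12.4 ± 2.05 CPM (counts scaled to a common library size; mean ± SD, n = 3) in control and 10.6 ± 1.76 (n = 5) in castrated epithelium. Fibroblasts held 27.4 ± 13.6 CPM in control and 19.9 ± 5.23 in castrated libraries. In vehicle cells Pten was at 22.9 ± 4.20 CPM (n = 4) in CaP2 and 11.1 ± 2.96 (n = 4) in CaP8. The counts sum all exons of a gene, so these values include reads from exons outside a deleted part and do not measure the deletion itself.

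The sorted populations differed as their labels state. Of 17128 genes tested with edgeR, 5586 were higher and 5686 lower in epithelium than in fibroblasts at a Benjamini-Hochberg adjusted p under 0.05. Krt8, a keratin of luminal epithelium, averaged 3372 ± 103 CPM in control epithelium and 135 ± 16.4 in control fibroblasts. Col1a1, a chain of the main fibrillar collagen, averaged 20.6 ± 13.1 and 11162 ± 4776 CPM. Among marker lists fixed before the data were examined, luminal epithelium had 20 of 21 measured members higher in epithelium and 1 lower, and fibroblast identity had 21 of 21 lower.

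Castration removes testicular androgen, and the first comparison asks which epithelial genes differ between castrated and control mice. The labels that set the groups give castration at week 10 but no time of collection. Age and time since castration thus cannot be told apart from androgen loss. Genes driven by the androgen receptor and genes of seminal secretion fell in castrated epithelium, while the MHC class II genes Cd74 and H2-Eb1, the acute-phase genes Hp and Saa3, the complement gene C3 and the chemokine gene Ccl20 rose. Probasin (Pbsn), a secretory protein under androgen control, fell by 8.87 on the log2 scale (adjusted p = 0.0049), from 392 to 0.827 CPM. Nkx3-1, a prostate homeobox gene that the androgen receptor activates, fell by 5.77 (adjusted p = 0.0013), and Fkbp5, a chaperone gene bound by the same receptor, fell by 2.37 (adjusted p = 8.7e-05). The BMP receptor gene Bmpr1b fell by 4.94 (adjusted p = 2.6e-06). Ar, which encodes the androgen receptor, changed by -0.05 (adjusted p = 0.96). For Pbsn, Nkx3-1, Fkbp5 and Bmpr1b every castrated library lay below every control library.

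Altogether 329 genes were higher and 435 lower in castrated than in control epithelium, and without control epithelium replicate 2 or 3 the calls numbered 357 and 371. Of 29 measured androgen-regulated genes, 14 were lower and 2 higher (16 and 5 adjusted over the list alone), and the list fell as a set (camera adjusted p = 4.1e-11, and adjusted p = 0.021 with an estimated correlation). Seminal vesicle secretory genes had 7 of 8 lower (8 adjusted over the list alone; camera adjusted p = 6.0e-40, and adjusted p = 9.2e-05 with an estimated correlation). Svs5 and Svs4, both of that list, fell by 11.09 and 8.54. The control libraries were uneven for Pbsn, at 11.1 CPM in replicate 1 and 493 and 672 CPM in the other control epithelial libraries. Nkx3-1 was low in replicate 1 too, at 1.63 CPM against 13.9 and 17.1, beside 0 to 0.432 CPM in castrated epithelium. Svs5 did not follow Pbsn, at 4364.5 CPM in replicate 1 and 17873 and 7421 CPM in the others. Whether the seminal vesicle transcripts came from prostate cells was not tested. The castrated libraries fall into 2 runs of library numbers, and Rn18s-rs5 took 4.67% and 2.88% of the counts in castrated epithelium replicates 1 and 2 and 15.8% to 16.9% in replicates 3 to 5. Against the same controls, the first run called 363 genes and the second 502, and Pbsn, at -8.90 and -8.84, was not called in either (adjusted p = 0.14 and 0.055), nor Svs4, at -7.24, in the first (adjusted p = 0.14).

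Among the rises, Rgs4, which shortens G-protein signalling, went from 24.2 to 464 CPM (log2 4.26, adjusted p = 5.0e-05). Cybb, the catalytic subunit of the phagocyte NADPH oxidase, went from 1.40 to 67.5 CPM (log2 5.59, adjusted p = 2.1e-04). Hp and Saa3 rose by 4.49 and 4.09, C3 by 2.78 and Ccl20 by 2.71. Cd74, the chaperone of MHC class II molecules, rose from 20.1 to 270 CPM (log2 3.75, adjusted p = 1.1e-04), and the class II gene H2-Eb1 rose by 2.55. The antigen presentation list had 6 of 22 members higher and 0 lower (8 and 1 adjusted over the list alone; camera adjusted p = 2.5e-11, adjusted p = 0.29 with an estimated correlation). The pan-leukocyte gene Ptprc was at 0.322 CPM in castrated and 0.392 in control epithelium. For Rgs4, Cybb, Hp, Saa3, C3, Ccl20, Cd74 and H2-Eb1 every castrated library lay above every control library. Of the TGFβ ligand genes, Tgfb2 rose from 15.0 to 47.1 CPM (log2 1.65, adjusted p = 4.4e-04), Tgfb1 changed by -0.10 (adjusted p = 0.96) and Tgfb3 by 0.27 (adjusted p = 0.73). The TGFβ target gene Serpine1, which encodes a plasminogen activator inhibitor, fell by 1.60 (adjusted p = 0.0017).

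**Figure D1:**
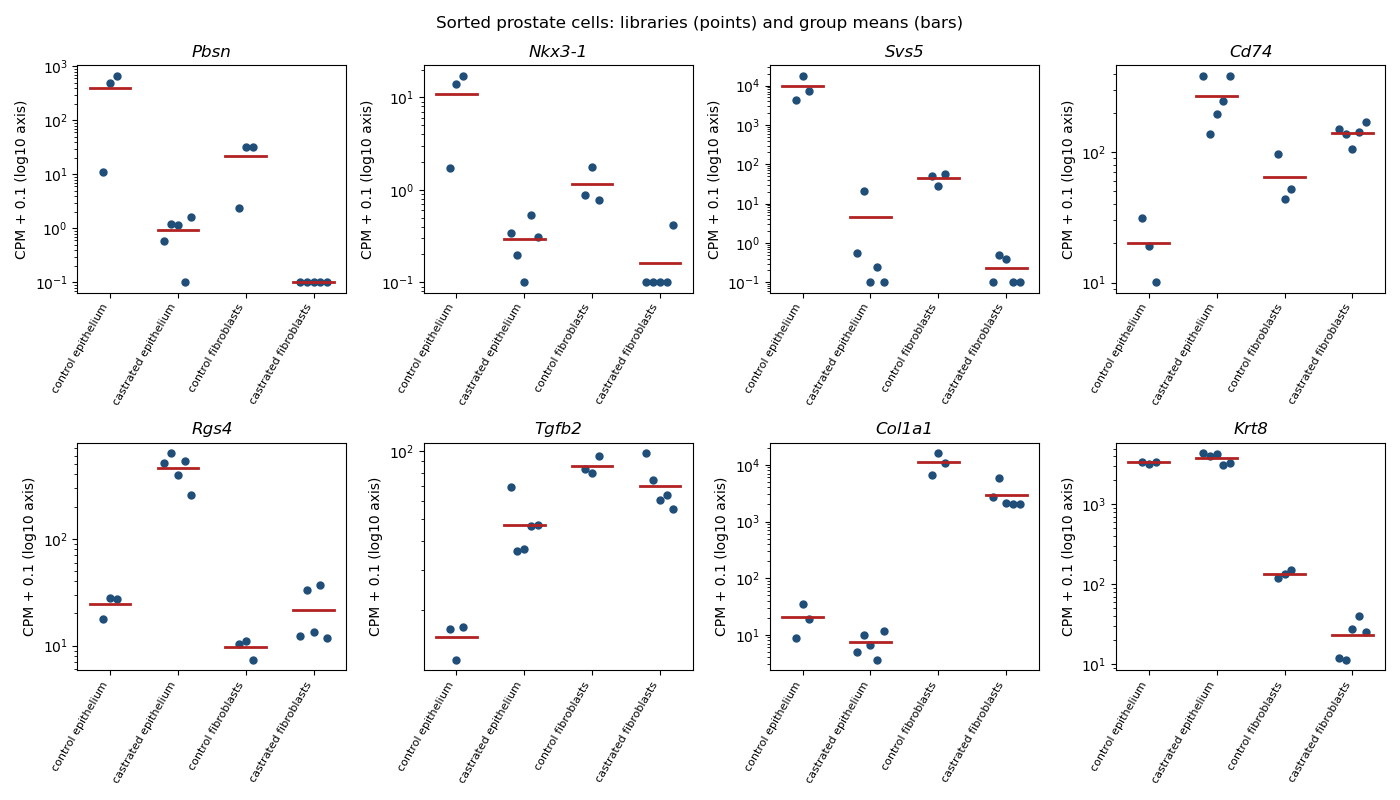
CPM of 8 genes per library (points, log10 axis with 0.1 CPM added) and group means (bars) in control (n = 3) and castrated (n = 5) epithelium and fibroblasts. Pbsn, Nkx3-1 and Svs5 are low in castrated epithelium and Cd74, Rgs4 and Tgfb2 are high, while Col1a1 and Krt8 are lower in castrated than in control fibroblasts.

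In fibroblasts the question is how the stroma differs between castrated and control mice, with the same limit. The collagen genes Col1a1 and Col3a1, the elastin gene Eln and the growth factor gene Igf1 fell in castrated fibroblasts, and so did markers of luminal epithelium, which a pure fibroblast sort would lack. Col1a1 fell by 1.92 (adjusted p = 0.027), from 11162 to 2945 CPM. Col3a1, a collagen of soft tissue, fell by 2.36 (adjusted p = 0.017), and Eln, which encodes elastin, by 2.7 (adjusted p = 0.0062). Igf1, a growth factor that stroma supplies to epithelium, fell by 1.57 (adjusted p = 0.038), from 1259 to 424 CPM. Chil1, a chitinase-like lectin gene, rose by 2.40 (adjusted p = 0.0016), and Plekha6, a gene of cell junctions, by 2.31 (adjusted p = 2.5e-05). For the collagen genes, Eln and Igf1 every castrated library lay below every control library, but some calls were lost with fewer libraries, at folds near those of all libraries. Col1a1 was not called when any 1 of 5 libraries was left out (log2 -1.57 to -2.02, adjusted p = 0.056 to 0.16), Igf1 when any 1 of 7 was (log2 -1.46 to -1.63, adjusted p = 0.051 to 0.12), and Col3a1 without control fibroblast replicate 2 (log2 -2.11, adjusted p = 0.088). Without the expression filter Col1a1, Col3a1 and Igf1 were not called either (adjusted p = 0.080, 0.060 and 0.093). With castrated fibroblast replicates 1 and 2 alone, Col1a1, Col3a1, Eln and Igf1 stood at -1.44, -2.05, -2.47 and -1.36 and were not called (adjusted p = 0.24, 0.12, 0.11 and 0.16), and Col3a1 was not with replicates 3 to 5 alone (log2 -2.69, adjusted p = 0.067).

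In all, 130 genes were higher and 523 lower in castrated than in control fibroblasts, and without control fibroblast replicate 2 the calls numbered 344. The libraries also differed in make-up, since 19283 to 21911 genes were detected in castrated and 22049 to 23338 in control fibroblasts, and Rn18s-rs5 took a mean of 14.9% and 9.04% of the counts. Whether this adds to the excess of falls was not tested. Of 21 measured luminal epithelium genes, 17 were lower and 0 higher (18 and 0 adjusted over the list alone; camera adjusted p = 6.0e-34, adjusted p = 0.0044 with an estimated correlation). Krt8 stood at 23.1 against 135 CPM (log2 -2.54) and Epcam, an epithelial adhesion gene, at 14 against 71.0 CPM (log2 -2.33). Androgen-regulated genes, 20 of 29 of them higher in epithelium, had 12 lower (17 adjusted over the list alone; adjusted p = 0.0056 with an estimated correlation). Extracellular matrix genes had 7 of 31 lower (11 adjusted over the list alone; camera adjusted p = 4.9e-06, adjusted p = 0.31 with an estimated correlation). Cell cycle genes had 10 of 30 lower (20 lower and 1 higher adjusted over the list alone; camera adjusted p = 1.8e-12, adjusted p = 0.19 with an estimated correlation). Myeloid cell markers had 0 of 18 members past the threshold and a median log2 change of 0.77 (0 adjusted over the list alone; camera adjusted p = 1.8e-05, adjusted p = 0.26 with an estimated correlation). After genes over 4-fold higher in epithelium were taken out, 73 genes were higher and 218 lower.

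Fgf9 (ENSMUSG00000021974.16), the ligand gene of the cell line experiment, stood at 24.5 CPM in control and 60.5 in castrated fibroblasts (log2 1.30, adjusted p = 0.080). Tgfb1 went from 14.9 to 28.5 CPM (log2 0.93, adjusted p = 0.093), and neither gene passed the threshold, though Fgf9 did without castrated fibroblast replicate 4 (adjusted p = 0.039) and by DESeq2 (log2 1.27, adjusted p = 0.042). The TGFβ-SMAD early target list rose as a set in castrated fibroblasts (camera adjusted p = 8.4e-05, adjusted p = 0.19 with an estimated correlation). It had 0 of 35 members past the threshold over all genes and 5 higher adjusted over the list alone.

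The change with castration differed between the sorted populations for 485 genes, 324 with a more positive change in epithelium and 161 with a more negative one. Tgfb2 (ENSMUSG00000039239.15) was among them (difference of log2 changes 1.94, adjusted p = 0.0025), as were Hp (7.81, adjusted p = 3.1e-04) and Krt8 (2.73, adjusted p = 0.0028). For Krt8 the difference comes mainly from the fall in fibroblast libraries, as its change in epithelium was 0.18 (adjusted p = 0.91; 3372 to 3832 CPM). Luminal epithelium genes had 13 of 21 members with a more positive change in epithelium (16 adjusted over the list alone; camera adjusted p = 7.1e-20, adjusted p = 0.055 with an estimated correlation), beside the 17 of 21 that fell in fibroblasts.

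TGFβ signals through SMAD transcription factors, and 1 h of treatment reads their early targets. In both lines it raised Gadd45g, Gadd45b, Snai1 and Skil and lowered Sat1. Gadd45g and Gadd45b, stress-induced growth-arrest genes, rose by 1.71 and 1.44 in CaP2 (adjusted p = 1.2e-04 and 8.4e-07) and by 1.56 and 1.21 in CaP8 (adjusted p = 2.6e-04 and 7.6e-06). Snai1, a repressor of epithelial genes, rose by 0.94 and 0.94 (adjusted p = 2.3e-05 and 5.8e-05), and Skil, a SMAD corepressor, by 0.78 and 0.62 (adjusted p = 0.014 and 0.0041). Smad7, the inhibitory SMAD, rose by 1.19 in CaP2 (adjusted p = 0.0037) and stood at 0.77 in CaP8 (adjusted p = 0.22). Sat1, an enzyme gene of polyamine breakdown, fell by 0.40 and 0.38 (adjusted p = 0.023 and 0.012). The ERK inhibitor gene Spry4 fell by 0.82 in CaP8 (adjusted p = 0.0019) and stood at -0.88 in CaP2 (adjusted p = 0.058). Skil in CaP2 was not called when any 1 of its 3 TGFβ libraries was left out (log2 0.76 to 0.81, adjusted p = 0.060 to 0.083), nor was Sat1 when any 1 of 4 libraries was left out in CaP2 (adjusted p = 0.051 to 0.15) or of 2 in CaP8 (adjusted p = 0.059 to 0.090). With only the TGFβ and vehicle libraries in the fit, Gadd45g, Skil, Smad7 and Sat1 were not called in CaP2 (adjusted p = 0.052, 0.26, 0.16 and 0.25), nor Gadd45b, Gadd45g, Snai1, Skil, Sat1 and Spry4 in CaP8 (adjusted p = 0.068, 0.082, 0.070, 0.16, 0.37 and 0.16).

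TGFβ against vehicle called 53 genes higher and 9 lower of 13374 in CaP2, and 37 and 9 of 13628 in CaP8. Of these, 23 rises and 2 falls were shared, where chance overlap gives 0.150 and 0.00636 (one-sided Fisher's exact p = 1.4e-48 and 1.6e-05). Per the file headers, vehicle replicates 1 to 3, TGFβ and SB431542 libraries came from 1 sequencing folder, and vehicle replicate 4, FGF9 and the double treatment from another. With the folder as a term, which sets TGFβ against vehicle 1 to 3, 337 genes were higher and 41 lower in CaP2 and 345 and 53 in CaP8. All 62 and all 46 pooled calls were kept, and Smad7 in CaP8 stood at 0.55 (adjusted p = 0.0038) and Spry4 in CaP2 at -0.68 (adjusted p = 0.027). The TGFβ-SMAD early targets had 6 of 32 members higher in CaP2 (8 higher and 1 lower adjusted over the list alone; camera adjusted p = 3.7e-16, adjusted p = 0.085 with an estimated correlation). In CaP8 they had 5 of 33 higher (10 adjusted over the list alone; adjusted p = 0.0071 with an estimated correlation).

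FGF9 binds FGF receptors and activates the MAP kinase ERK, and 0.5 h of treatment reads the immediate response. The ERK target Fos rose in both lines, while feedback inhibitors and growth factor genes that ERK usually induces were lower with FGF9 than with vehicle, as were TGFβ-SMAD targets. Fos and Klf2 are single genes and do not stand for the ERK immediate-early list, whose result with FGF9 is not given here. Fos, an immediate-early transcription factor gene, rose by 1.7 in CaP2 (adjusted p = 7.1e-07) and 1.33 in CaP8 (adjusted p = 8.5e-04). Klf2, another transcription factor gene, rose by 1.05 and 1.7 (adjusted p = 0.010 and 1.4e-06), but was not called in CaP2 with only these groups in the fit (adjusted p = 0.073). Dusp6, a phosphatase that switches ERK off, fell by 1.26 and 0.64 (adjusted p = 1.7e-08 and 2.6e-06), and the ERK pathway inhibitor genes Spry4 by 1.82 and 1.76 and Spry2 by 1.62 and 1.04. The EGF receptor ligand genes Areg and Hbegf fell by 3.01 and 2.60 in CaP2 and by 2.06 and 1.75 in CaP8. Skil fell by 1.77 and 1.52, and Hes1, a Notch and TGFβ target, by 1.85 and 2.03. In CaP8, the calcineurin inhibitor gene Rcan1 fell by 2.73 (adjusted p = 4.7e-10).

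FGF9 against vehicle called 1497 genes higher and 1764 lower in CaP2, and 1564 and 1739 in CaP8. With the sequencing folder as a term, which leaves vehicle replicate 4 as the only comparator and assumes that it varies like the other groups, the calls dropped to 58 higher and 230 lower in CaP2 (227 of the pooled calls kept, 1 with its sign changed). In CaP8 they dropped to 137 and 322 (359 kept, 1 with its sign changed). Against that single library, Fos stood at 2.15 and 1.64 and Klf2 at 2.22 and 2.14. Dusp6 stood at -1.36 and -0.76 and Spry4 at -2.28 and -2.02. Areg stood at -3.61 and -2.13, Hbegf at -2.20 and -1.78, Skil at -1.23 and -1.28 and Hes1 at -1.63 and -1.85. Other large changes were not called within the folder. In CaP2, mt-Co2, a mitochondrial respiratory gene, went from 3.17 to 2.51 (adjusted p = 0.58). In the pooled fit it stood at 0.76 without FGF9 replicate 3 (adjusted p = 0.20) and was not called without vehicle replicate 1 or 2 (adjusted p = 0.056 and 0.054) or with only these groups in the fit (adjusted p = 0.081). Sprr2h, a cornified envelope gene, went from -3.75 to -0.18 with the folder term (adjusted p = 0.89).

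Of 27 FGF-ERK feedback genes, 20 were lower and 1 higher with FGF9 in CaP2 (20 and 3 adjusted over the list alone; adjusted p = 1.2e-06 with an estimated correlation). In CaP8, 17 were lower and 2 higher (18 and 2; 1.8e-06). TGFβ-SMAD early targets had 19 of 32 lower in CaP2 (22 adjusted over the list alone; adjusted p = 0.0087 with an estimated correlation), and 18 of 33 lower and 2 higher in CaP8 (20 and 2; 0.0023). Of 30 cell cycle genes, 16 were higher and 3 lower in CaP2 and 23 higher and 1 lower in CaP8 (20 and 4, and 27 and 1, adjusted over the list alone). As a set they were higher in the pooled fit (camera adjusted p = 1.3e-04 and 2.3e-12), but not called there with an estimated correlation (adjusted p = 0.36 and 0.24) or by camera with the folder as a term (adjusted p = 0.73 and 0.23).

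**Figure D2:**
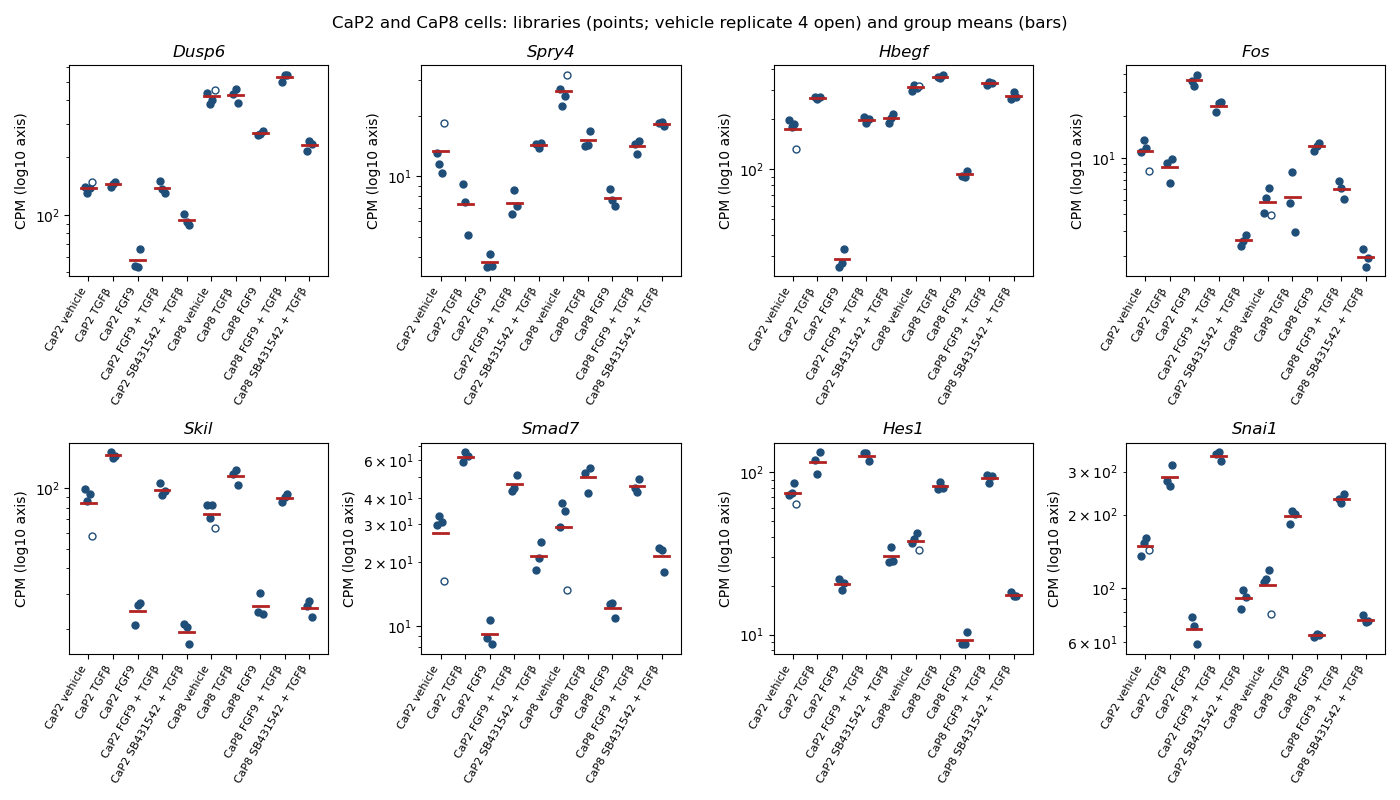
CPM of 8 genes per library (log10 axis) in CaP2 and CaP8 under each treatment, with vehicle replicate 4 drawn as an open point because it shares its sequencing folder with the FGF9 and the double treatment libraries. Dusp6, Spry4, Hbegf, Skil and Hes1 lie lower with FGF9 alone than with vehicle, and higher again with both ligands.

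Adding TGFβ to FGF9 asks whether the ligands act together, and FGF9 libraries with and without TGFβ lie in 1 sequencing folder. This comparison was added after the file headers were read. Hbegf, Skil and Dusp6, which were lower with FGF9 than with vehicle, were higher with both ligands than with FGF9, a pair of comparisons that share the FGF9 libraries. Etv4, also lower with FGF9 in CaP2, was not called there (log2 0.06, adjusted p = 0.97). Hbegf rose by 2.79 in CaP2 and 1.83 in CaP8 (adjusted p = 1.1e-10 and 2.8e-14), and Fosb, an AP-1 subunit gene, by 3.17 and 3.09 (5.3e-11 and 2.8e-14). Skil rose by 1.99 and 1.78, Smad7 by 2.33 and 1.91 and Dusp6 by 1.26 and 0.98. Tgfb1 rose by 2.76 in CaP2 (adjusted p = 2.3e-05) and stood at 1.07 in CaP8 (adjusted p = 0.094), where the folder term, DESeq2, no expression filter and a fit of these groups alone called it (adjusted p = 0.0030, 0.022, 2.6e-05 and 0.0018). The calls were 255 higher and 31 lower in CaP2 and 183 and 52 in CaP8. TGFβ-SMAD targets had 16 of 32 higher in CaP2 and 13 of 33 in CaP8 (17 and 22 adjusted over the list alone; adjusted p = 6.2e-05 and 2.0e-06 with an estimated correlation).

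The interaction term asks whether TGFβ changed a gene more in the presence of FGF9 than alone. It was called for 79 genes above and 8 below 0 in CaP2, and for 70 and 9 in CaP8. Without vehicle replicate 4 the calls numbered 274 and 283, with the folder as a term 275 and 283, and the fewest with 1 library left out were 48 in CaP2, without TGFβ replicate 2, and 64 in CaP8, without FGF9 replicate 2. Egr3, an immediate-early factor gene, had an interaction of 2.90 in CaP2 (adjusted p = 0.0098) and 2.61 in CaP8 (adjusted p = 7.9e-06), Dusp6 of 1.20 and 0.96 (1.0e-05 and 7.4e-06), and Skil of 1.21 and 1.16 (0.0098 and 1.5e-04). FGF-ERK feedback genes had 10 of 27 members above 0 in CaP2 and 8 of 27 in CaP8 (16 and 15 adjusted over the list alone; adjusted p = 2.3e-07 and 4.7e-07 with an estimated correlation). TGFβ-SMAD targets had 10 of 32 and 9 of 33 above 0 (13 and 12; 0.0019 and 1.6e-04). Against vehicle, the double treatment called 1214 genes higher and 1155 lower in CaP2 and 1309 and 1303 in CaP8, which the folder term reduced to 172 and 50 and to 145 and 113.

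SB431542 blocks the receptor kinase, and this comparison reads what it changes with TGFβ present. No group had SB431542 alone, so loss of the TGFβ response is not separated from effects on basal levels. In CaP2, Skil ran from 16.8 to 21.2 CPM with SB431542 and TGFβ, below its 58.0 to 99.5 CPM in vehicle. Smad7, at 18.2 to 24.8 CPM, lay within its vehicle range of 16.3 to 32.7 CPM. Skil, Smad7, Serpine1 and Egr2 were lower with the inhibitor in both lines. Of these, TGFβ alone had raised Skil in both lines and Smad7 and Egr2 in CaP2, and Serpine1 stood at 0.72 and 0.80 with TGFβ (adjusted p = 0.48 and 0.33). Skil fell by 2.90 in CaP2 and 2.17 in CaP8 (adjusted p = 1.4e-08 and 3.3e-10), and Smad7 by 1.55 and 1.23 (adjusted p = 1.1e-04 and 0.0086). Serpine1 fell by 0.96 and 1.35 (adjusted p = 0.045 and 0.020), and Egr2, an immediate-early factor gene, by 4.26 and 3.94 (1.3e-10 and 3.3e-06). Cxcl1, a neutrophil chemokine gene, rose by 2.11 and 1.87 (adjusted p = 1.7e-06 and 0.0039), and the LDL receptor gene Ldlr by 0.68 and 0.64 (adjusted p = 2.0e-06 and 5.8e-06). Serpine1 was not called when any 1 of the 6 libraries was left out in CaP2 (adjusted p = 0.077 to 0.13), or any 1 of 4 in CaP8 (adjusted p = 0.055 to 0.098), at folds of -0.88 to -1.09 and -1.19 to -1.35, and Smad7 was not called in CaP8 without SB431542 replicate 3 (adjusted p = 0.053). Cxcl1 was not called in CaP8 with only these groups in the fit (adjusted p = 0.11).

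SB431542 with TGFβ against TGFβ called 966 genes higher and 953 lower in CaP2, and 491 and 435 in CaP8, all within 1 sequencing folder. TGFβ-SMAD targets had 14 of 32 lower and 3 higher in CaP2 (15 and 3 adjusted over the list alone; camera adjusted p = 1.3e-12, adjusted p = 0.053 with an estimated correlation). In CaP8 they had 14 of 33 lower (16 adjusted over the list alone; adjusted p = 8.0e-04 with an estimated correlation). Cholesterol synthesis genes had 7 of 23 higher in CaP2 (8 adjusted over the list alone; camera adjusted p = 9.6e-05, adjusted p = 0.46 with an estimated correlation) and 17 of 23 in CaP8 (18 adjusted over the list alone; adjusted p = 0.0053 with an estimated correlation).

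To separate the choice of genes from their test, the rises called with TGFβ in each line were read in the other line. The 53 genes raised in CaP2 fell by a median of 0.53 with SB431542 in CaP8 (31 lower and 0 higher; camera p = 5.4e-73, p = 3.7e-08 with an estimated correlation). Of the 37 raised in CaP8, 36 were measured in CaP2 and fell by a median of 1.00 (33 lower and 0 higher; camera p = 2.6e-84, p = 2.3e-08 with an estimated correlation). With genes chosen under the folder term the medians were -0.32 in CaP8 (65 of 334 lower and 2 higher), not called with an estimated correlation (p = 0.050), and -0.62 in CaP2 (164 of 343 lower and 1 higher; p = 0.018 with an estimated correlation). Against vehicle, SB431542 with TGFβ called 1036 genes higher and 946 lower in CaP2 and 356 and 374 in CaP8. On that comparison the same genes had medians of -0.13 in CaP8 (19 lower and 7 higher, 29 of 53 below 0) and -0.30 in CaP2 (16 lower and 1 higher). The genes chosen under the folder term had medians of 0.07 in CaP8 (30 lower and 25 higher; p = 0.78 with an estimated correlation) and -0.28 in CaP2 (51 lower and 5 higher; p = 0.29 with an estimated correlation).

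CaP2 and CaP8 differed widely before treatment, with 4265 of 14457 genes higher and 4068 lower in CaP8 than in CaP2 vehicle cells. Dusp6 was higher in CaP8 by 1.58 and Etv4, an ETS factor gene induced by ERK, by 1.61 (adjusted p = 2.0e-18 and 2.3e-09). The FGF receptor gene Fgfr2 was lower in CaP8 (log2 -6.54, adjusted p = 4.0e-12). The size of this difference is uncertain, as all CaP8 libraries together held 13 counts of Fgfr2, and it stood at -9.35 with the folder as a term. The TGFβ response differed between the lines for 1 gene by edgeR, Sphk1, which makes sphingosine 1-phosphate (-0.85, adjusted p = 0.024), with 644 genes at an unadjusted p under 0.05 and 1 call by DESeq2. Sphk1 was not called when any 1 of 7 libraries was left out (log2 -0.79 to -0.86, adjusted p = 0.051 to 0.12). The FGF9 response differed for 556 genes, 428 more positive and 128 more negative in CaP8, and for 31 with the sequencing folder as a term. Rcan1 (-3.33, and -3.33 with the folder as a term) and Chac1, a glutathione-degrading enzyme gene of the unfolded protein response (-2.21 and -2.18), differed in the pooled fit (adjusted p = 1.1e-10 and 2.1e-08), and the folder term, with 1 vehicle library per line beside FGF9, left their size alike. FGF9 rises and falls overlapped between the lines in 632 and 898 genes, where chance gives 174 and 226, and in 29 and 141 with the folder as a term, where chance gives 0.615 and 5.70.

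The last comparison asks whether the TGFβ genes of the cell lines move in the castrated prostate. The 23 genes raised by TGFβ in both lines changed by a median of 0.12 in castrated epithelium (camera p = 0.24, p = 0.49 with an estimated correlation) and 0.05 in castrated fibroblasts (camera p = 0.083, p = 0.32 with an estimated correlation), so neither moved as a set. By edgeR 0 of the 23 were called in epithelium, where 6 had an unadjusted p under 0.05 and DESeq2 called 1. In fibroblasts edgeR and DESeq2 each called 1, and 3 had an unadjusted p under 0.05.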

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

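All tests weighed in the last 3 paragraphs of this part were chosen after the result was seen, while the tests for outlying libraries and for differences between groups were planned.

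A library stood apart from the rest of its group in 12 of 92 groups of values examined, where chance alone gives about 1 in 20. Vehicle replicate 4 of CaP2 lay far from the other vehicle libraries for Egr3 (gap to the nearest library as a share of the range, Dixon's Q, 0.886), Klf2 (0.909), Sprr2h (0.948) and Gadd45g (0.893). Vehicle replicate 4 of CaP8 did so for Rcan1 (0.909), Gadd45b (0.857) and Gadd45g (0.880). This is the vehicle library that shares its sequencing folder with the FGF9 libraries. In CaP2 it lay closer to the FGF9 libraries (root mean square log2 difference 0.433) than to vehicle replicates 1 to 3 (0.607), and in CaP8 likewise (0.439 and 0.597). The 18S share of CaP2 vehicle replicate 3, at 12.1%, stood below the other CaP2 vehicle libraries (0.930). In castrated epithelium, replicate 4 was the highest for Ptprc (0.739) at 0.792 CPM. Castrated epithelium replicate 2 was the highest for Svs4 (0.935) at 37.2 CPM and for Svs5 (0.979) at 21.3 CPM. Col1a1 was highest in castrated fibroblast replicate 2 (0.830), at 5912 CPM.

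Castration changed 485 genes by different amounts in epithelium and fibroblasts, by the interaction term of the edgeR fit. The differences of the log2 changes were 7.81 for Hp, 2.73 for Krt8 and 1.94 for Tgfb2, where that of Krt8 comes mainly from its fall in fibroblasts. The FGF9 response differed between CaP8 and CaP2 for 556 genes, with differences of -2.21 for Chac1 and -3.33 for Rcan1. The TGFβ response differed for 1 gene, Sphk1 (-0.85).

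Epithelial genes were lower in castrated than in control fibroblasts. RNA with the make-up of the sorted control epithelium would put basal and luminal markers at a like share of their epithelial level, but basal markers stood at 0.972% (median of 10 genes) and luminal ones at 3.72% (median of 14), which speaks against that source. Luminal RNA alone may account for much of these falls. The luminal share fell from 3.23% to 4.11% of the epithelial level in control fibroblast libraries to 0.301% to 1.10% in castrated ones. It predicted a median of 0.594 of the observed fall over 293 genes, with 165 of them within 2-fold. The share was set from luminal genes in these same libraries, and the 293 genes were chosen for falling there, so it was not tested independently. For the 7 extracellular matrix genes that fell it predicted a median of 0.0196% of the fall, with 0.00878% for Col1a1 and 0.0426% at most, so luminal RNA is argued against as the source of these falls. Over all 230 falls of genes not over 4-fold higher in epithelium, it predicted a median of 0.0121 of the fall (quartiles 7.7e-04 and 0.0630), with 1 within 2-fold. The choice of these genes keeps this share low by construction, so it does not test luminal RNA as their source. Other sources were not told apart either. For the matrix genes a response of the stroma to androgen loss stays open, and the labels do not tell it from a different mix of fibroblasts.

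FGF-ERK feedback genes were lower with FGF9 than with vehicle, though ERK usually induces them. With the sequencing folder as a term, which rests on 1 vehicle library per line, the median change of the list was -1.11 in CaP2 and -0.67 in CaP8, which as a fold argues against the folder as the whole source, as far as a single vehicle library per line can. Libraries of SB431542 with TGFβ carrying FGF9 labels are argued against too, if the SB431542 labels themselves hold. The list stood at 0.32 and 0.0193 against vehicle in the SB431542 libraries. Other label errors were not tested. An early drop in these transcripts at 0.5 h may be a feature of the cells, which was not tested. A difference in culture or handling between vehicle replicate 4 and the FGF9 wells may also give it. The double treatment libraries, treated wells of the same folder, do not settle this, as TGFβ was present and genes differed. Dusp6 ran from 130 to 151 CPM there in CaP2 and from 499 to 543 in CaP8, beside 148 and 454 in vehicle replicate 4. Spry4 ran from 6.52 to 8.60 and from 12.9 to 14.9, beside 18.3 and 31.8.

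MHC class II genes were higher in castrated epithelium (median log2 change 2.90 over 4 genes). Myeloid cells carried past the sort would bring their abundant transcripts, but Lyz2 went from 6.0 to 8.08 CPM while Cd74 went from 20.1 to 270. In castrated fibroblasts Lyz2 stood at 107 CPM beside a Cd74 of 141, so myeloid cells of the kind found there are argued against. The 18 myeloid markers had a median change of 0.43, with Cd14 called higher (81.3 to 176 CPM, though at 16.4 and 21.5 in fibroblasts). Leukocytes of the make-up in castrated fibroblast libraries would also raise Ptprc, Cd53, Coro1a and Laptm5, which rose by a median of 1.64% of what the Cd74 rise needs (at most 12.5%, for Cd53), so they are argued against as the whole source. B or plasma cells are argued against likewise, as Igkc, Jchain and Ighm rose by 8.36%, 6.11% and 0.0571% of the need. Neutrophil markers (median change 2.13 over 7 genes, at 0.547 CPM, 1 called higher and 1 lower) and T and NK markers (0.82 over 6, 1 called higher) lie too low to decide alone. Cybb rose by 5.59 to 67.5 CPM, above its 9.24 CPM in castrated fibroblasts, so a leukocyte of another make-up, rich in class II and Cybb, was not excluded. Class II expression by the epithelial cells themselves may be the source and was not tested by any protein or single-cell measurement in these data.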

How the results depend on the processing

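The tests with the sequencing folder as a term, with epithelium-high genes removed, and of both ligands against FGF9 were chosen after the data were seen, while the other alternatives were planned. No named gene or list past the threshold reversed its direction under the alternatives run for it. With TGFβ genes chosen under the folder term, the median with SB431542 and TGFβ against vehicle in CaP8 went from -0.13 to 0.07, and that in castrated fibroblasts from 0.05 to -0.11, neither called as a set then. Among genes not named, that term changed the sign of 1 FGF9 call in each line, 1 call of both ligands in CaP8 and 49 calls of the vehicle line difference (45 with the replicate block). Of the values of named genes under the alternatives, 1499 kept their direction and their side of the threshold, 69 were no longer called and 21 became called, and of those of lists, 129 kept theirs and 13 were no longer called. The RLE size factors and the joined tables left the counts within 1.5 times of those reported. Where no construction is named, the cause was not tested. At these depths the spread between libraries limits small changes most, as 20% of simulated 2-fold changes were recovered for castration in epithelium.

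DESeq2 called 1171 genes for castration in epithelium, 1296 in fibroblasts and 873 for their difference. In CaP2 it called 147 with TGFβ, 179 for the interaction and 466 for both ligands against FGF9, and in CaP8 188, 151 and 401. Without an expression filter the calls were 430 with TGFβ, 379 for the interaction and 789 for both ligands against FGF9 in CaP2, 560, 338 and 502 in CaP8, and 31 for the line difference of the TGFβ response. For castration in epithelium, the castrated libraries of the first run of library numbers alone gave 363 calls and those of the second 502, with fewer libraries by construction. Without genes over 4-fold higher in epithelium, castration in fibroblasts called 291 genes, with fewer genes tested by construction.

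With only the groups compared in the fit, which leaves fewer libraries to estimate the spread, castration in fibroblasts called 275 genes. In CaP2 the calls were 20 with TGFβ, 1118 with FGF9, 989 with both ligands, 642 for SB431542 with TGFβ against vehicle and 585 for both ligands against FGF9. In CaP8 they were 1, 1074, 345, 182 and 752, and 1717 for SB431542 with TGFβ against TGFβ. The cause of the higher counts among these was not tested. A 1.5-fold minimum left 577 of the genes shared between lines for FGF9 and 15 for TGFβ, since it removes smaller changes by construction.

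With the sequencing folder as a term, TGFβ called 378 genes in CaP2 and 398 in CaP8, FGF9 288 and 459, both ligands 222 and 258, the interaction 275 and 283, SB431542 with TGFβ against TGFβ 2997 and 1925, and both ligands against FGF9 604 and 583. SB431542 with TGFβ against vehicle called 1579 in CaP8, the FGF9 line difference 31 and the TGFβ line difference 3. The overlaps between lines were 170 for FGF9 and 222 for TGFβ. By construction this term leaves vehicle replicate 4 as the only vehicle for FGF9 and both ligands, a lone library assumed to vary like the other groups, and vehicle replicates 1 to 3 for TGFβ and SB431542.

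Whether the replicate numbers pair the samples was not settled. Deviations of same-numbered libraries correlated by -0.12 to 0.19 in the prostate, -0.10 to 0.08 in CaP2 and -0.13 to 0.12 in CaP8. A library matched its own number best in 22 of 40, 26 of 60 and 21 of 60 cases, not compared with chance. Most correlations lay under 0.1. Control epithelium and fibroblasts 1 to 3 stood at 0.189, 0.111 and 0.115, a hint of shared animals from the data, not the design. Control and castrated epithelium 2, from different mice, stood at 0.107. With the number as a block, TGFβ called 381 genes in CaP2 and 428 in CaP8, FGF9 5078 and 5360, both ligands 4618 and 4975, the interaction 322 and 334, SB431542 with TGFβ against TGFβ 2910 and 1885, and both ligands against FGF9 592 and 605. SB431542 with TGFβ against vehicle called 1597 in CaP8, the FGF9 line difference 2171 and the TGFβ line difference 2. Only vehicle has a replicate 4, so the block takes that library out of these comparisons by construction.

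Leaving out 1 library at a time, castration in epithelium called 357 (without control epithelium 2; 371 without 3) to 849 genes, in fibroblasts 344 (control fibroblast 2) to 863, and their difference 257 (control epithelium 2; 269 without 3 and 288 without control fibroblast 2) to 614. Epithelium against fibroblasts ran from 10914 to 11247 and the vehicle line difference from 7854 to 8358. In CaP2, TGFβ ran from 32 (TGFβ 3; 38 without 2) to 377 (vehicle 4). FGF9 in CaP2 ran from 1925 (vehicle 1; 2044 without 2 and 2055 without 3) to 5154 (vehicle 4). Both ligands in CaP2 ran from 1038 (double treatment 3; 1100 without 1 and 1049 without 2; 1083, 1183 and 1194 without vehicle 1, 2 and 3) to 4666 (vehicle 4). The CaP2 interaction ran from 48 (TGFβ 2; 57 without 1, 55 without 3 and 56 without double treatment 3) to 274 (vehicle 4). SB431542 with TGFβ in CaP2 ran from 1132 (SB431542 2; 1143, 1139 and 1170 without TGFβ 1, 2 and 3) to 1969 against TGFβ, and from 1184 (SB431542 3; 1186 without 2) to 2561 against vehicle. Both ligands against FGF9 in CaP2 ran from 176 (double treatment 2; 179 without 3) to 237.

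In CaP8, TGFβ ran from 22 (TGFβ 3; 26 without 2) to 401 (vehicle 4) and FGF9 from 1967 (FGF9 3; 2106 without 1 and 2185 without vehicle 3) to 5344 (vehicle 4). Both ligands in CaP8 ran from 1313 (double treatment 2; 1380 without 1 and 1330 without 3; 1471, 1495 and 1437 without vehicle 1, 2 and 3) to 5018 (vehicle 4), and the interaction from 64 to 283 (vehicle 4). SB431542 with TGFβ in CaP8 ran from 478 (SB431542 3; 539 without 1, 552 without TGFβ 1 and 617 without TGFβ 3) to 652 against TGFβ, and from 312 (SB431542 3; 414 without 1 and 457 without 2) to 1583 (vehicle 4) against vehicle. Both ligands against FGF9 in CaP8 ran from 133 (FGF9 1; 144 without 2 and 156 without double treatment 2) to 200. The TGFβ line difference ran from 0 (without CaP2 vehicle 1, CaP2 TGFβ 1 or 3, CaP8 vehicle 2 or 3, or CaP8 TGFβ 1 or 2) to 2 (CaP2 vehicle 4). The FGF9 line difference ran from 208 (CaP8 FGF9 2) to 1512 (CaP2 vehicle 4), with 340, 241 and 323 without CaP2 vehicle 1, 2 and 3, 350 and 231 without CaP2 FGF9 2 and 3, 281, 344, 315 and 1198 without CaP8 vehicle 1, 2, 3 and 4, and 271 and 220 without CaP8 FGF9 1 and 3.

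Other splits of the samples were refitted, at most 100 per comparison. Chance is excluded for castration in epithelium (764 calls, at most 14 in another split) and fibroblasts (653, at most 231). It is too for epithelium against fibroblasts (11272, at most 7434) and the vehicle line difference (8333, at most 2703). The same holds for SB431542 with TGFβ against vehicle in CaP2 (1982, at most 781). For the interaction (87 calls in CaP2 and 79 in CaP8), 3 of 100 drawn splits gave as many in each, the real one included. The highest gave 4618 and 5093. For the castration difference (485 calls) it gave 146. These splits also undo the treatment effects, so they cannot test whether effects differ. Chance is not argued against for FGF9 against vehicle (3261 and 3303 calls in CaP2 and CaP8, at most 4913 and 5249) or both ligands against vehicle (2369 and 2612, at most 4754 and 5132). In these the split as large follows the sequencing folder, with vehicle 1 to 3 against vehicle 4 and the treated libraries, and the values within the folder are 288, 459, 222 and 258. Nor is it argued against for TGFβ against vehicle (62 and 46, at most 315 and 281), or for SB431542 with TGFβ against vehicle in CaP8 (730, at most 819), where the highest split also sets vehicle 1 to 3 against all other libraries. With TGFβ this split calls several times the real count, which points to a structure of the samples. Values within the folder are 378, 398 and 1579. The FGF9 (556, at most 5369) and TGFβ (1, at most 362) line differences also ask whether effects differ, so splits cannot decide. With 3 libraries against 3 the splits are too few for a share under 0.05: SB431542 with TGFβ against TGFβ called 1919 and 926, and both ligands against FGF9 286 and 235, with 0 in every other split.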

Other observations

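Gene lists that the comparisons above did not describe also moved, and their tests were planned, apart from that of both ligands against FGF9. Without treatment, CaP8 vehicle cells stood above CaP2 vehicle cells for 6 of 7 measured luminal epithelium genes (0 lower; camera adjusted p = 2.7e-07, and adjusted p = 0.0057 with an estimated correlation), though levels were low, as for Krt8 at 2.20 CPM in CaP2 and 6.0 in CaP8. Genes of castration-tolerant and proximal luminal progenitor cells had 8 of 12 members higher in CaP8 and 2 lower (adjusted p = 0.0062 with an estimated correlation), and FGF-ERK feedback genes had 17 of 27 higher and 4 lower (adjusted p = 0.0057 with an estimated correlation). With SB431542 and TGFβ against TGFβ alone, ERK immediate-early genes fell as a set in both lines, with 10 of 25 members lower and 2 higher in CaP2 and 12 of 26 lower and 1 higher in CaP8 (adjusted p = 0.0095 and 8.2e-04 with an estimated correlation). Paracrine growth factor genes had 6 of 20 members higher and 0 lower with both ligands than with FGF9 alone in CaP2, and 6 of 18 higher and 0 lower in CaP8 (adjusted p = 5.1e-05 and 2.0e-06 with an estimated correlation).

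In castrated fibroblasts, 10 of 20 genes of the castration-tolerant and proximal luminal progenitor list were lower than in control fibroblasts and 0 higher (camera adjusted p = 4.3e-12, adjusted p = 0.044 with an estimated correlation). The list is epithelial, with 18 of 20 members higher in epithelium than in fibroblasts, and the level of abundant luminal genes in fibroblast libraries fell beside it, from 3.72% to 0.646% of the epithelial level. Seminal vesicle genes, which control fibroblast libraries also held, had 5 of 8 members lower and 0 higher (adjusted p = 0.044 with an estimated correlation). Svs5 averaged 45.0 CPM in control and 0.133 CPM in castrated fibroblasts, against 9886 CPM in control epithelium.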
